A study of Mus musculus with 16 samples.

How the data were processed

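Per the submitters' processing notes, the deposited values are log2 signals made with RMA, which corrects background, normalizes quantiles and summarizes each probe set, from Affymetrix mouse arrays. Per the labels' protocols, RNA was taken up in Trizol and labelled for the arrays at a core facility. The file holds 35556 probes and 16 arrays, with values from 1.84 to 14 and 0 missing, and all its columns were used. Probes were given genes by the probe table supplied with the series: 23410 probes are in it, 21789 with 1 gene symbol and 1621 with several, and the 12146 others were not tested as genes. Gene ids matched 21698 probes to the reference of mouse genes (assembly GRCm38.p6), which changed 0 symbols. The genome build behind the array design is not given in the sources used here.

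A probe was kept if it exceeded its array's 25th percentile on at least 4 arrays, which left 17930 probes. The probe with the highest mean stood for each of the 861 genes with more than 1 kept probe, giving 16427 genes. Among the named genes, 2 had probes of which only 1 was called: Fbl had 0.2 and 0.59 for the CD28 effect in knockout, and Fdft1 -0.55 and -0.34 between genotypes under anti-CD3. Among the genes not tested, Tcf7, Nfkb1 and Ddx3y lacked a probe with a single symbol, and Il10, Bhlhe41, Mx1 and Cd86 were too dim. Some gene lists lost many members in these ways. CD8 and NK cell markers kept 8 of 18, and erythroid and platelet markers 6 of 18.

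Differences were tested with limma (version 3.58.1 under R 4.3.3), with a mean per group fitted over 16 arrays and moderated variances (12 residual degrees of freedom, 4.92 prior). The Benjamini-Hochberg adjusted p had to be under 0.05. The 5 comparisons were the CD28 effect in wild type, the same in knockout, the genotype under each stimulus, and the interaction. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Groups, comparisons, gene lists and the first alternatives were chosen before the data were examined.

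Replicates of the same number were tested for pairing. Correlations of their deviations from the group mean were 0.16 to 0.37 for the CD28 effect in wild type, 0.22 to 0.51 in knockout, 0.18 to 0.45 between genotypes under anti-CD3 and 0.2 to 0.59 under anti-CD3 plus anti-CD28, against medians of -0.06, -0.16, -0.13 and -0.37 for unlike numbers. All comparisons were therefore also fitted with the replicate number as a block, which left 9 residual degrees of freedom. Deviations cancel out within a group, so positive values for like numbers push those for unlike numbers down. The medians are thus no independent baseline, and a parting of the numbers in sets could also raise the values for like numbers.

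The 23 gene lists were T cell cytokines, chemokines and their receptors, activation and costimulation receptors, naive and quiescence genes, DNA replication and G1/S, mitosis, glycolysis, amino acid transport and ATF4 targets, cholesterol synthesis, MYC and ribosome biogenesis, NF-kB targets, AP-1, NFAT and immediate early genes, interferon response, circadian clock, helper lineage transcription factors, apoptosis, heat shock and stress, and markers of B cells, myeloid and dendritic cells, CD8 and NK cells, regulatory T cells, memory T cells, and erythroid cells and platelets. Each was tested with limma's camera at its preset correlation between genes of 0.01, and again with the correlation estimated from the arrays, on ranks, and with fry. Members were also counted after adjusting over the list alone. Named genes are the 8 largest called changes in each direction whose groups do not overlap, the 4 members of each list with the smallest p, and a panel fixed beforehand.

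Known changes were added to simulated values, drawn with each gene's own mean and SD and independent between genes, to see what limma recovers. Changes of 1.5-fold were recovered in 67.2%, 68.7%, 68.7%, 79.1% and 40.3% of cases in the 5 comparisons and changes of 2-fold in 94%, 95.5%, 95.5%, 98.5% and 76.1%. A shift of -0.5 of the DNA replication list was called by camera (adjusted p = 3.13e-46) with 0 other lists. Since the simulated genes were independent, this does not test false calls among correlated genes. On the arrays the estimated correlation of this list was 0.47. Alternatives covered scaling, the filter, the choice of probe, the variance model, array weights, the block, leaving out each array, and, added later, the 2 sets of replicate numbers and the Xist level.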

Results

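Gene expression was measured in naive CD4+ T cells of B6 mice with and without the transcription factor Dec1, a basic helix-loop-helix repressor encoded by Bhlhe40. The cells were sorted from spleen and lymph nodes as naive and CD25 negative. They were kept for 24 h at 1000000 cells per ml in medium with 10% serum, together with latex beads. The beads carried either anti-CD3, which engages the T cell receptor complex, or anti-CD3 and anti-CD28, which also engages the costimulatory receptor CD28. Each combination of genotype and stimulus had 4 arrays, which gave the 4 groups WT_CD3, WT_CD3CD28, KO_CD3 and KO_CD3CD28 (WT, wild type; KO, knockout). The labels number the replicates 1 to 4 without saying that they came from separate animals, so p-values measure the spread among these samples, part of which may be technical.

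The 16 arrays held log2 values of 35556 probes, with array medians of 6.64 to 6.97, and 16427 genes were tested. The number of arrays limits the precision. Correlations across the tested genes were 0.97 to 0.995 between arrays of a group and 0.9093 to 0.9955 between arrays of different groups. The first principal component held 65.6% of the variance and parted the stimuli. In the deviations of each array from its group mean, the first component held 39.6% of the variance, and replicates 1 and 2 of all 4 groups lay on its other side from replicates 3 and 4. The labels name no batch that would part them. Xist, the RNA expressed from the inactive X chromosome of female cells, was at 10.44 to 11.36 in WT replicate 1, KO replicate 2 and KO replicate 4 under both stimuli, and at 5.09 to 5.80 on the other arrays. The Y-linked gene Kdm5d was at 5.69 to 6.15 on the arrays with high Xist and at 9.62 to 10.12 on the others.

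Bhlhe40 was measured first, since it is the gene the knockout targets. Its log2 level was 7.56 ± 0.42 (SD, n = 4) in WT_CD3 and 9.51 ± 0.71 in WT_CD3CD28, against 5.53 ± 0.32 in KO_CD3 and 5.88 ± 0.14 in KO_CD3CD28. In limma, the knockout cells were lower by -2.03 on the log2 scale under anti-CD3 (SE 0.27, adjusted p = 0.00548) and by -3.62 under anti-CD3 plus anti-CD28, at least a 12.3-fold difference (adjusted p = 3.76e-06). Both groups' values stayed apart in each stimulus. With replicates 3 and 4 alone the difference under anti-CD3 was -1.99 with an adjusted p of 0.0969. Its probe ranked between the 17.1 and 36.5 percentiles of all probes on knockout arrays and between the 53.1 and 88.4 percentiles on wild-type arrays, so the knockout values are near background and the differences are lower bounds. Which part of the gene was deleted is not given in the sources used here.

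**Figure D1:**
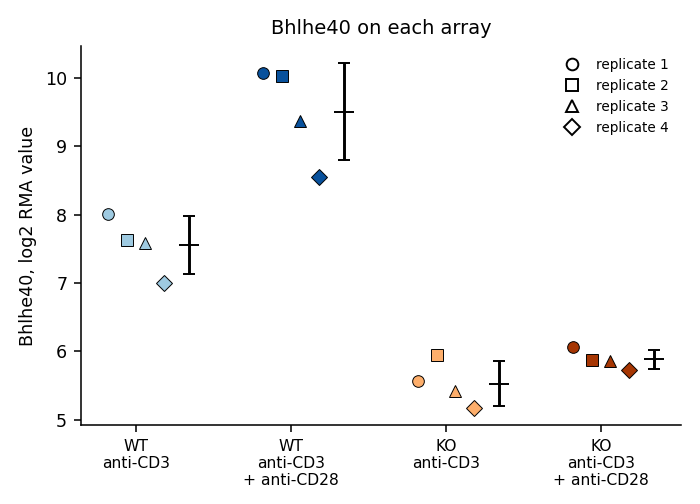
Log2 RMA value of Bhlhe40 on each of the 16 arrays (y axis) by group (x axis), with the marker shape giving the replicate number and the bars the group mean and SD. The knockout arrays lie between 5.18 and 6.07 and the wild-type arrays between 7 and 10.07.

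The first comparison asked what CD28 costimulation adds to anti-CD3 in wild-type cells. Il2, the growth factor of T cells, rose from 7.15 ± 0.27 to 11.17 ± 0.71 (SD, n = 4), a 16.2-fold change in limma (log2 4.02, SE 0.37, adjusted p = 4.86e-07). Genes of cell division rose with it: the mitotic checkpoint kinase Bub1 by 3.48 (SE 0.35), the chromosome motor Kif4 by 3.53 (SE 0.32) and the spindle protein Hmmr, near background under anti-CD3, by at least 3.46 (SE 0.16), each with 4 arrays per group whose values did not overlap. The NK cell receptor chain Klrd1 fell by 3.43 on the log2 scale (SE 0.25, adjusted p = 4.69e-08), a lower bound since it reached near background, and the interferon-inducible Ifi214 by 3.04 (SE 0.34, adjusted p = 3.73e-06). In all, 2630 genes were higher and 2140 lower, 4770 or 29% of those tested. With the replicate number as a block 5800 were called, and with replicates 3 and 4 alone 2650. Centring each array on its median moved the median of all genes from -0.03 to 0.061 and gave 3241 higher and 1438 lower genes, or 69.3% higher against 55.1%.

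Among the lists fixed beforehand, the cell cycle moved furthest. Of 29 tested genes of mitosis 28 rose (28 adjusted over the list alone), with a median log2 change of 2.55 (limma's camera, adjusted p = 2.2e-33). With an estimated correlation the list had an adjusted p = 0.046, and 0.056 when the replicate block was fitted as well. Cenpf, a kinetochore protein, rose by 2.96 (SE 0.12) and the proliferation marker Mki67 by 2.99 (SE 0.27, adjusted p = 4.91e-07). Of 42 genes of DNA replication and G1/S 38 rose (38 adjusted over the list alone; median 1.24, adjusted p = 8.1e-24, and adjusted p = 0.08 with an estimated correlation). Among them were the origin recognition subunit Orc1 (2.12, SE 0.11), the replication initiator Mcm10 (1.99, SE 0.15) and the cell cycle transcription factor E2f8 (3.10, SE 0.29). Of 31 genes of MYC and ribosome biogenesis 19 rose and none fell (22 adjusted over the list alone; median 0.58, adjusted p = 1.1e-09, and adjusted p = 0.26 with an estimated correlation). They included Dkc1, which modifies ribosomal RNA, at 0.75 (SE 0.08), and Myc itself rose by 0.62 (SE 0.13, adjusted p = 0.00146).

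Genes of resting T cells moved the other way. Of 27 naive and quiescence genes 23 fell (24 adjusted over the list alone), with a median of -0.81 (adjusted p = 5.2e-15). It had an adjusted p = 0.046 with an estimated correlation, and 0.056 with the replicate block added. The IL-7 receptor chain Il7r fell by 2.34 (SE 0.21, adjusted p = 3.75e-07), the thioredoxin-binding protein Txnip by 2.05 (SE 0.1), the PI3K inhibitor Pik3ip1 by 1.57 (SE 0.15) and the transcription factor Klf3 by 1.32 (SE 0.11).

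Of 23 T cell cytokines 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0075, and adjusted p = 0.046 with an estimated correlation, or 0.056 with the block added). Besides Il2, Lif rose by 2.59 (SE 0.2, adjusted p = 7.52e-08), Lta by 1.45 (SE 0.21), Il3 by 3.71 (SE 0.82, adjusted p = 0.00227) and Ifng by 0.69 (SE 0.21, adjusted p = 0.0205), while Ltb fell by 1.32 (SE 0.17). The call of Ifng was lost without WT_CD3CD28 replicate 1, WT_CD3 replicate 2 or WT_CD3 replicate 3 (adjusted p up to 0.0702). Il3 spread widely in WT_CD3CD28, at 8.27 ± 1.96 (SD, n = 4), and at 4.56 ± 0.43 in WT_CD3 it was near background, so its change is a lower bound. Csf2, also near background in WT_CD3 at 5.45, differed by at least 1.12 (SE 0.49, adjusted p = 0.101), with an adjusted p of 0.0187 when the replicate number was a block and of 0.0254 at the lowest when WT_CD3CD28 replicate 3 or 4 was left out.

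Of 27 activation and costimulation receptors 10 rose and 3 fell (11 and 4 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.15). The transferrin receptor Tfrc rose by 1.30 (SE 0.15), the IL-2 receptor chain Il2ra by 0.92 (SE 0.19, adjusted p = 0.0014) and the inhibitory receptor Ctla4 by 0.63 (SE 0.22, adjusted p = 0.0376), while Tnfrsf9 fell by 0.95 (SE 0.18, adjusted p = 0.000674). The call of Ctla4 was lost after quantile normalization (adjusted p = 0.0879) and without any of WT_CD3CD28 replicates 1, 3 and 4 and WT_CD3 replicates 2, 3 and 4 (adjusted p up to 0.103). Cd28 differed by -0.36 (SE 0.16, adjusted p = 0.0941, and 0.0017 with the replicate block) and the costimulatory receptor Tnfrsf4 by 0.66 (SE 0.26, adjusted p = 0.0736, and 0.000667 with the block). Both passed without WT_CD3CD28 replicate 4 (adjusted p = 0.0203 and 0.0218). Restricted to replicates 3 and 4, Tnfrsf9 differed by -0.77 (adjusted p = 0.0821).

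Metabolic genes shifted more modestly. Of 20 genes of cholesterol synthesis 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.37, adjusted p = 0.00052, and adjusted p = 0.34 with an estimated correlation), with Idi1 at 1.35 (SE 0.2) and Sqle, a rate-limiting enzyme, at 0.72 (SE 0.12). Of 29 genes of amino acid transport and ATF4 targets 11 rose and 2 fell (11 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.026, and adjusted p = 0.58 with an estimated correlation). The mitochondrial folate enzyme Mthfd2 rose by 1.29 (SE 0.12) and the serine synthesis enzyme Psat1 by 1.11 (SE 0.14). The call of this list was lost without WT_CD3CD28 replicate 1 or 2 (adjusted p up to 0.093), with replicates 3 and 4 alone (0.083) and after quantile normalization (0.11).

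Markers of other cell types that a sort could carry along also moved. Of 18 B cell markers 8 fell (9 adjusted over the list alone; median -0.27, adjusted p = 0.00026, and adjusted p = 0.08 with an estimated correlation), Cd79a among them (-0.89, SE 0.16, a lower bound since it reached near background). Of 23 myeloid and dendritic cell markers 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.0063, and adjusted p = 0.08 with an estimated correlation). The MHC class II chain H2-Ab1 fell by 0.89 (SE 0.19). The mean of 11 T cell identity genes also fell, by 0.55 on the log2 scale (95% interval -0.77 to -0.32), against -0.44 for the B cell and -0.34 for the myeloid list.

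The lists of chemokines and their receptors (5 higher and 3 lower), glycolysis (5 and 3), NF-kB targets (6 and 5), AP-1, NFAT and immediate early genes (6 and 9), interferon response (2 and 7) and circadian clock (1 and 3) were not called, with camera adjusted p from 0.12 to 0.94. Nor were those of helper lineage transcription factors (5 and 6), apoptosis (4 and 4), heat shock (7 and 1), CD8 and NK cell markers (4 and 4), regulatory T cell markers (6 and 2), memory markers (4 and 6) or erythroid and platelet markers (0 and 0), at 0.099 to 0.97. Single members changed strongly within them: the chemokine receptor Ccr8 rose by 1.97 (SE 0.34), the survival factor Bcl2l1 by 1.79 (SE 0.32, adjusted p = 0.00035), while its opponent Bcl2l11 fell by 1.16 (SE 0.1) and the follicular helper factor Bcl6 by 1.88 (SE 0.17). The CD8 and NK cell list had a median of 0.18 and a mean of -0.36, since Klrd1 fell by far more than other members rose.

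**Figure D2:**
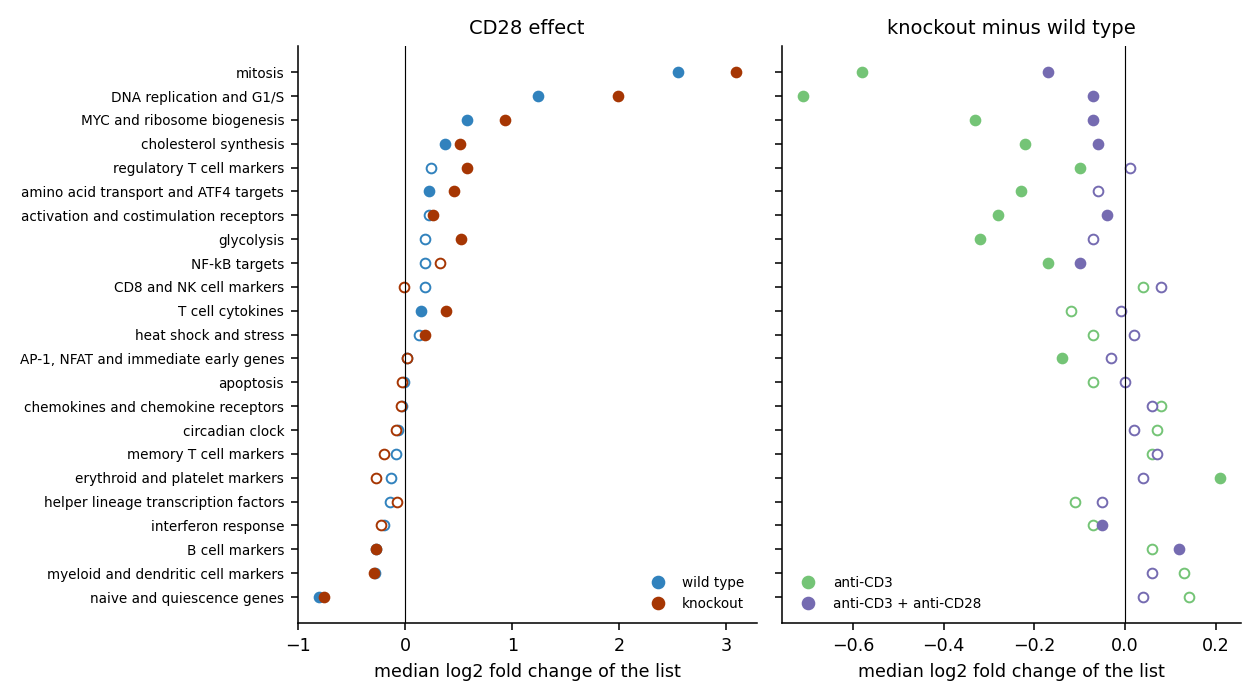
Median log2 fold change of each of the 23 gene lists (x axis) for the CD28 effect in wild type and knockout (left) and for knockout minus wild type under each stimulus (right). Filled points mark lists called by camera with the preset correlation; mitosis has medians of 2.55 and 3.09 on the left, and DNA replication medians of -0.71 and -0.07 on the right.

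The same question was put to knockout cells. Il2 rose by 3.93 (SE 0.37, adjusted p = 3.01e-07), from 6.75 ± 0.3 to 10.68 ± 0.9 (SD, n = 4), and Lif by 2.68 (SE 0.2). Bub1, Kif4 and E2f8, near background under anti-CD3, rose by at least 4.78 (SE 0.35), 4.42 (SE 0.32) and 4.10 (SE 0.29) and Mki67 by 3.73 (SE 0.27), while Klrd1 fell by 3.71 (SE 0.25) and Il7r by 2.75 (SE 0.21). Bhlhe40 differed by 0.35 (SE 0.27, adjusted p = 0.323). limma called 3357 genes higher and 2888 lower, 6245 or 38% of those tested. With the replicate block 7441 were called, with replicates 3 and 4 alone 2896, and with every probe tested on its own 9853. Median centring moved the median of all genes from -0.063 to 0.071 and gave 4283 higher and 1430 lower genes, 75% higher against 53.8%.

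All lists called in wild type were called here with the same direction. Of 42 genes of DNA replication and G1/S 41 rose (41 adjusted over the list alone; median 1.99, camera adjusted p = 1.1e-28), and of 29 genes of mitosis 28 (28 adjusted over the list alone; median 3.09, 1.9e-29). Both had an adjusted p = 0.072 with an estimated correlation. Orc1 rose by 2.90 (SE 0.11) and Mcm10 by 2.71 (SE 0.15). Of 31 genes of MYC and ribosome biogenesis 26 rose (27 adjusted over the list alone; median 0.93, adjusted p = 7.1e-13, and adjusted p = 0.13 with an estimated correlation), and Myc by 1.10 (SE 0.13). Of 27 naive and quiescence genes 23 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.76, adjusted p = 1.1e-11, and adjusted p = 0.072 with an estimated correlation), with Txnip lower by -2.24 (SE 0.1).

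Of 27 activation and costimulation receptors 11 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.0046, and adjusted p = 0.074 with an estimated correlation). Il2ra rose by 1.49 (SE 0.19), Ctla4 by 1.48 (SE 0.22), Il2rb by 1.24 (SE 0.19), Tfrc by 1.92 (SE 0.15), Tnfrsf4 by 1.35 (SE 0.26) and the costimulator Icos by 0.78 (SE 0.21, adjusted p = 0.00657). Of 15 regulatory T cell markers, several of which are also activation receptors, 8 rose (8 adjusted over the list alone; median 0.58, adjusted p = 0.023, and adjusted p = 0.14 with an estimated correlation), among them Tnfrsf18 by 0.92 (SE 0.26) and Ikzf2 by 0.74 (SE 0.15). Of 23 cytokines 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.38, adjusted p = 0.026, and adjusted p = 0.074 with an estimated correlation). Il3 rose by 2.56 (SE 0.82, adjusted p = 0.0209), a call lost without KO_CD3CD28 replicate 1 or 2 (adjusted p up to 0.0823) and with a trended, robust variance (0.0541), and Tnf by 0.95 (SE 0.23). The changes of Il3 and Csf2 are again lower bounds. Csf2 differed by 0.73 (SE 0.49, adjusted p = 0.257). The regulatory list was not called without KO_CD3 replicate 4 (0.055), and the cytokine list without KO_CD3 replicate 3 (0.054). With replicates 3 and 4 alone Tnf, Tnfrsf18 and Ikzf2 were not called (adjusted p = 0.234, 0.11 and 0.0572).

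Of 18 genes of glycolysis 9 rose and 3 fell (9 and 3 adjusted over the list alone; median 0.52, adjusted p = 0.024, and adjusted p = 0.38 with an estimated correlation), with Tpi1 at 1.48 (SE 0.19) and Pgk1 at 0.76 (SE 0.08). Of 20 genes of cholesterol synthesis 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 3.7e-05, and adjusted p = 0.19 with an estimated correlation), Sqle by 1.07 (SE 0.12). Of 29 amino acid and ATF4 genes 14 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 0.00093, and adjusted p = 0.37 with an estimated correlation). Of 20 heat shock genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.13 with an estimated correlation), with the mitochondrial chaperonin Hspd1 at 0.56 (SE 0.07). The glycolysis call was lost without KO_CD3 replicate 4 (0.063). After quantile normalization the calls of glycolysis (0.11), heat shock (0.11), activation receptors (0.077) and B cell markers (0.068) were lost.

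B cell markers fell in 9 of 18 cases (9 adjusted over the list alone; median -0.27, adjusted p = 0.01, and adjusted p = 0.19 with an estimated correlation), with Ms4a1 lower by at least -1.25 (SE 0.23), at a level near background. Of 23 myeloid and dendritic cell markers 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.29, adjusted p = 0.0033, and adjusted p = 0.072 with an estimated correlation). Tyrobp fell by 0.74 (SE 0.16), while the lysosomal thiol reductase Ifi30 rose by 1.59 (SE 0.18). The lists not called were chemokines (4 higher and 5 lower), NF-kB targets (6 and 4), AP-1, NFAT and immediate early genes (10 and 4), interferon response (2 and 9), circadian clock (1 and 5), helper lineage factors (5 and 5), apoptosis (5 and 5), CD8 and NK cells (4 and 4), memory markers (4 and 6) and erythroid and platelet markers (0 and 3). Their adjusted p ranged from 0.088 to 0.93. The interferon list passed without KO_CD3CD28 replicate 3 (0.041). Bcl2l1 rose by 1.87 (SE 0.32, adjusted p = 0.000164).

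Of the 2630 genes that CD28 raised in wild type, 2418 were also raised in knockout (91.9%), and of 2140 lowered genes 1676 were also lowered (78.3%). Independent lists would share 537.5 and 376.2, and no gene was called in opposite directions. Over the 4770 genes called in wild type, the slope through 0 of the knockout effect on the wild-type effect was 1.105 (Pearson r 0.971 across genes, which are not independent replicates). Genes chosen on 2 wild-type replicates and measured on the other 2 gave slopes of 1.046 to 1.216. Computed within each replicate number, the slopes were 1.11, 1.161, 1.16 and 0.808 (SD 0.169), so the excess over 1 was smaller than their spread.

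**Figure D3:**
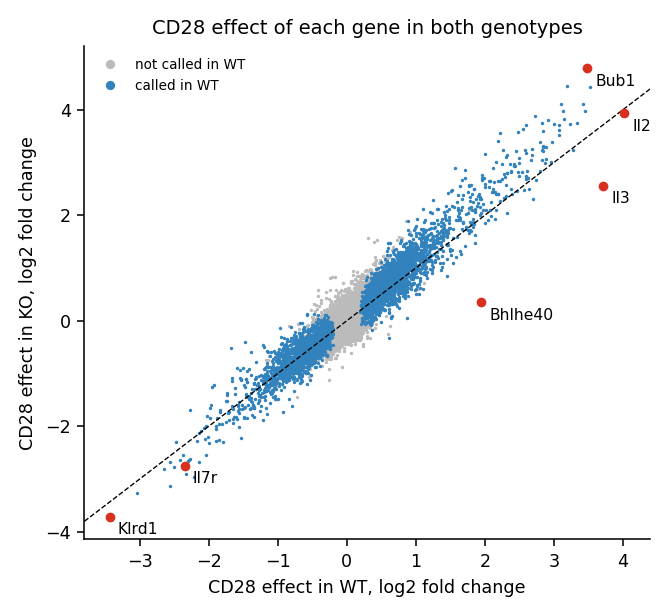
Log2 fold change by CD28 of each of the 16427 tested genes in wild type (x axis) and knockout (y axis), with genes called in wild type in blue and a dashed line of equal effects. Il2 lies at 4.02 and 3.93, close to the line, and Bhlhe40 at 1.95 and 0.35, below it.

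The size of the CD28 effect differed between replicates 1 and 2 and replicates 3 and 4, for genes of both genotypes. In limma 635 genes differed in this respect, 415 of them with a lower effect in replicates 3 and 4. The sets were chosen from the first component of the same arrays, so these calls and their p-values are no independent support. Parting the numbers in the other 2 ways gave 0 and 0. Those fits left the difference between the sets in the residual spread, so their 0 and 0 give no backing either. The following genes were chosen after the effects had been seen. Since Il1a, Il3 and Csf2 were near background under anti-CD3, their effects are lower bounds. The cytokine Il1a had a mean effect of 4.52 in replicates 1 and 2 and of 0.49 in replicates 3 and 4 (adjusted p = 5.34e-10), Il3 of 4.84 and 1.43, the chemokine Ccl3 of 4.25 and 1.69 and Csf2 of 1.77 and 0.08. Il2 had 4.65 and 3.3 (adjusted p = 0.00137), Bcl2l1 2.14 and 1.52, and Il7r -2.93 and -2.16. Larger in replicates 3 and 4 were the effects on the cytokine signalling inhibitor Socs2 (1.15 and 3.98) and on Il2ra (0.7 and 1.7, adjusted p = 0.000103). In replicates 3 and 4 Socs2 was at 5.49 to 6.37 under anti-CD3, near background, so its effect of 3.98 is a lower bound. Mki67 (3.65 and 3.07, adjusted p = 0.115) and Myc (0.81 and 0.91, adjusted p = 0.674) were not called.

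**Figure D4:**
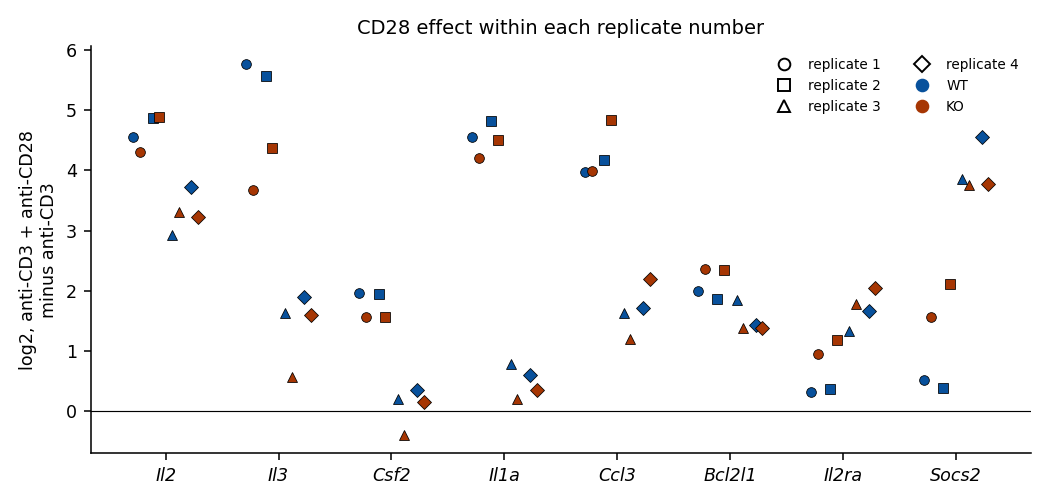
Log2 CD28 effect (y axis) on Il2, Il3, Csf2, Il1a, Ccl3, Bcl2l1, Il2ra and Socs2 (x axis) within each replicate number of each genotype. The mean effect on Il1a is 4.52 in replicates 1 and 2 and 0.49 in replicates 3 and 4.

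Knockout and wild-type cells were then compared under anti-CD3 alone. Genes of DNA replication were lower in the knockout: Orc1 by -0.77 (SE 0.11, limma adjusted p = 0.00586), the replicative helicase subunits Mcm3 by -1.15 (SE 0.19, adjusted p = 0.0161) and Mcm5 by -1.03 (SE 0.17, adjusted p = 0.0161), and the DNA ligase Lig1 by -0.96 (SE 0.16, adjusted p = 0.0163), with 4 arrays per group. Besides Bhlhe40, the largest falls were of Cenpk, a kinetochore protein (-1.46, SE 0.27), the neuritin gene Nrn1 (-1.35, SE 0.2), the ubiquitin ligase subunit Dtl (-1.32, SE 0.22), the cold shock protein Ybx3 (-1.28, SE 0.2), E2f8 (-1.24, SE 0.29, a lower bound since KO_CD3 was near background), Ncapg2 (-1.23, SE 0.28) and the DNA methylation cofactor Uhrf1 (-1.22, SE 0.24). The signalling inhibitor Spry1 was lower by -0.82 (SE 0.11, adjusted p = 0.00548). In all, 46 genes were higher and 123 lower, 169 or 1.03% of those tested, and 77 of them changed at least 1.5-fold.

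With the replicate number as a block, 877 genes were higher and 1077 lower (1954), and all 169 were among them. Leaving out 1 array moved that count to 262 and 682 without WT_CD3 replicate 3 and 4 and to 662 and 359 without KO_CD3 replicate 1 and 2. The 2 genotypes' arrays did not overlap for 2413 genes (14.7%, against 2.86% by chance). Leaving out 1 array moved the count of 169 to 26, 60 and 7 without WT_CD3 replicate 1, 2 and 3, and to 37, 11 and 452 without KO_CD3 replicate 1, 2 and 3. Replicates 1 and 2 alone gave 1388 genes and replicates 3 and 4 alone gave 0 in limma. Median centring gave 13 higher and 248 lower genes, 4.98% higher against 27.2%, and the stricter filter on dim probes 15.4% higher. The Xist level was high on 1 WT_CD3 array and 2 KO_CD3 arrays, and with it as a covariate 49 genes were called, all of them among the 169.

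Bhlhe40, Orc1, Nrn1 and Spry1 were called whichever array was left out (adjusted p at most 0.047). Ybx3 was lost without WT_CD3 replicate 3 (0.0703), and Mcm3, Mcm5, Lig1 and Dtl without WT_CD3 replicate 3 or KO_CD3 replicate 2 (adjusted p up to 0.0711, 0.0703, 0.0703 and 0.0797). Cenpk was lost without KO_CD3 replicates 1 or 2 or WT_CD3 replicate 3 (up to 0.102). Uhrf1 was lost without any of these 3 or WT_CD3 replicate 1 (up to 0.123). E2f8 passed only without KO_CD3 replicate 3 among the 8 arrays compared, and reached 0.168. Ncapg2 was lost without replicate 1 or 2 of either genotype or WT_CD3 replicates 3 or 4 (up to 0.174). After quantile normalization Ncapg2 was not called (0.0501), and with a random block neither were E2f8 (0.0615) and Ncapg2 (0.0503). With the Xist level as a covariate Bhlhe40, Orc1, Mcm3, Mcm5, Lig1, Cenpk, Dtl, Nrn1, Ybx3 and Spry1 stayed called. Fitted with only the 8 arrays compared, Bhlhe40, Spry1 and Ybx3 remained called among the genes named here, and 5 genes in all.

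Of 42 genes of DNA replication and G1/S 18 fell (33 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 5.2e-25, and adjusted p = 0.18 with an estimated correlation). Its mean level was lower by -0.67 (95% interval -0.98 to -0.36), by -0.74 within replicates 1 and 2 and by -0.59 within replicates 3 and 4. On the same arrays 11 T cell identity genes had a mean difference of -0.21 (95% interval -0.44 to 0.01). Of 29 mitosis genes 2 fell, Cenpe (-0.89, SE 0.18, to near background) and Bub1b (-0.77, SE 0.17), and 20 did so when adjusted over the list alone (median -0.58, adjusted p = 4.4e-12, and adjusted p = 0.22 with an estimated correlation). With the block 29 and 18 members of these lists were called lower. Mki67 differed by -0.92 (SE 0.27, adjusted p = 0.0917, and 0.0102 with the block).

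**Figure D5:**
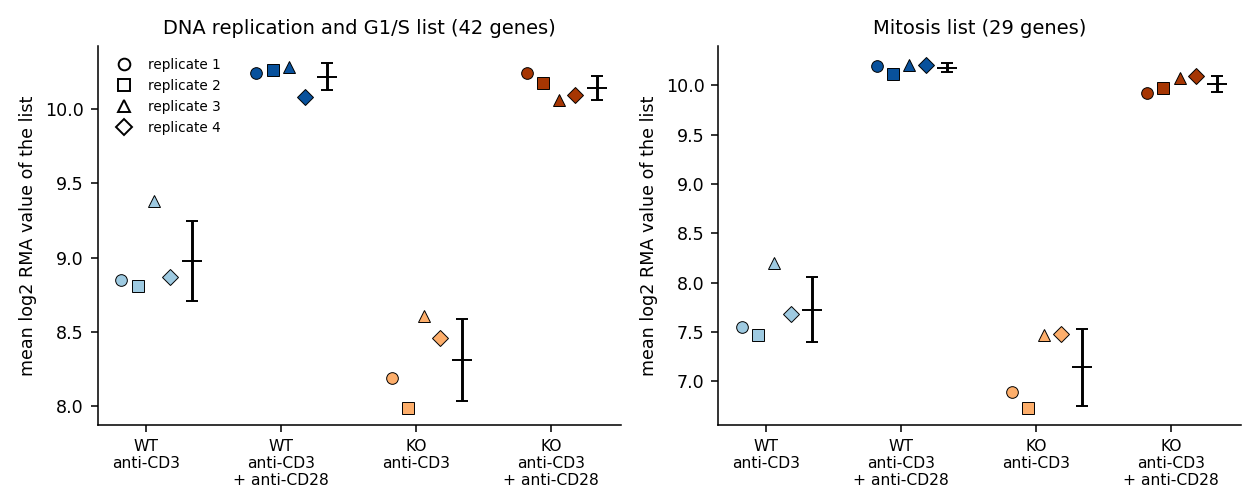
Mean log2 RMA value of the 42 DNA replication and G1/S genes (left) and the 29 mitosis genes (right) on each array (y axis) by group (x axis), with the marker shape giving the replicate number and the bars the group mean and SD. The DNA replication mean lies at 8.81 to 9.38 in WT_CD3 and 7.99 to 8.61 in KO_CD3, and at 10.06 to 10.28 in both groups with CD28.

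Of 31 genes of MYC and ribosome biogenesis 4 fell (11 adjusted over the list alone and 19 with the block; median -0.33, camera adjusted p = 2e-10, and adjusted p = 0.22 with an estimated correlation). They were Myc (-0.60, SE 0.13, limma adjusted p = 0.0421), Rrs1 (-0.66, SE 0.12, 0.0202), Nop58 (-0.44, SE 0.09, 0.0351) and Dkc1 (-0.40, SE 0.08, 0.0351). After quantile normalization Myc, Nop58 and Dkc1 were not called (0.109, 0.117 and 0.077). Rrs1 was lost without WT_CD3 replicates 1 or 3 or KO_CD3 replicate 2 (up to 0.102), Nop58 and Dkc1 without any of WT_CD3 replicates 1, 2 and 3 and KO_CD3 replicates 1 and 2 (up to 0.13 and 0.141). Myc was lost without any of the 8 arrays but WT_CD3 replicate 4 (up to 0.141).

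Of 27 activation and costimulation receptors 1 fell (9 adjusted over the list alone and 8 with the block), Tfrc by 0.64 on the log2 scale (SE 0.15, adjusted p = 0.0481). The list was called (median -0.28, adjusted p = 2.4e-05) and held with an estimated correlation (adjusted p = 0.038). Tfrc was lost after quantile normalization (0.0692) and without any of WT_CD3 replicates 1, 2 and 3 and KO_CD3 replicates 1 and 2 (up to 0.181). Passing only with the block were Ctla4 (-0.83, adjusted p = 0.07, and 0.0177 with the block), Il2rb (-0.73, 0.0665 and 0.0146), Pdcd1 (-0.72, 0.0665 and 0.0168), Tnfrsf4 (-0.73, 0.126 and 0.00586), Tnf (-0.84, 0.0789 and 0.0246) and the transcription factor Irf4 (-0.58, 0.0775 and 0.0137). Ctla4 also passed without KO_CD3 replicate 3 or 4 (0.0379 at the lowest), and Pdcd1 (0.0456), Tnf (0.0364) and Mki67 (0.0281) without KO_CD3 replicate 3. Il2 differed by -0.40 (SE 0.37, adjusted p = 0.496), Il2ra by -0.56 (0.115) and Il7r by 0.53 (0.147). Csf2 was near background in both groups (-0.03, adjusted p = 0.976).

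Metabolic lists were lower in the knockout by camera. Glycolysis had no member called over all genes, 6 lower and 1 higher adjusted over the list alone and 6 lower with the block (18 genes, median -0.32, adjusted p = 9.6e-05, and adjusted p = 0.22 with an estimated correlation). Tpi1 differed by -0.80 (adjusted p = 0.0518, and 0.0109 with the block). Of 29 amino acid and ATF4 genes 1 fell, Psat1 (-0.63, SE 0.14, adjusted p = 0.0473), with 2 adjusted over the list alone and 11 with the block (median -0.23, adjusted p = 0.00051, and adjusted p = 0.38 with an estimated correlation). Mthfd2 differed by -0.48 (adjusted p = 0.0522, and 0.0141 with the block). Psat1 was lost after quantile normalization (0.0685) and without any of the 8 arrays but KO_CD3 replicate 3 and WT_CD3 replicate 4 (up to 0.174), while Tpi1 and Mthfd2 passed without either of these (0.0336 and 0.0349 at the lowest). Cholesterol synthesis had no member called, 0 adjusted over the list alone and 3 lower with the block (20 genes, median -0.22, adjusted p = 4.4e-05, and adjusted p = 0.26 with an estimated correlation).

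Of 36 AP-1, NFAT and immediate early genes 1 fell, Spry1 (2 adjusted over the list alone and 6 with the block; median -0.14, adjusted p = 0.0048, and adjusted p = 0.22 with an estimated correlation). The regulatory T cell list (15 genes, 0 called, 4 lower adjusted over the list alone and 3 with the block; median -0.10) had an adjusted p of 0.02, and adjusted p = 0.22 with an estimated correlation. It was lost without WT_CD3 replicates 1 or 2 or KO_CD3 replicate 3 (up to 0.066) and with replicates 3 and 4 alone (0.059). NF-kB targets (21 genes, 0 called and 0 adjusted over the list alone; median -0.17) had an adjusted p of 0.044, and adjusted p = 0.63 with an estimated correlation. They were lost after quantile normalization (0.45) and without WT_CD3 replicates 1 or 2 or KO_CD3 replicates 3 or 4 (up to 0.18). Erythroid and platelet markers (6 genes, 0 called and 0 adjusted over the list alone) were higher with a median of 0.21 (adjusted p = 0.042, and adjusted p = 0.3 with an estimated correlation). They were lost after quantile normalization (0.077), with the Xist level as a covariate (0.061) and without KO_CD3 replicates 1, 2 or 4 or WT_CD3 replicates 3 or 4 (up to 0.099).

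No member of the remaining lists was called by limma over all genes. Their camera adjusted p values were 0.59 for cytokines, 0.73 for chemokines, 0.33 for naive and quiescence genes, 0.4 for interferon response, 0.79 for circadian clock, 0.2 for helper lineage factors and 0.73 for apoptosis. They were 0.12 for heat shock, 0.79 for B cell, 0.24 for myeloid, 0.81 for CD8 and NK cell and 0.89 for memory markers. Naive and quiescence genes passed after quantile normalization (0.0022), upwards, and with replicates 1 and 2 alone (0.0026). Among the 46 higher genes the largest changes were of the lysophosphatidic acid receptor Lpar6 (0.64, SE 0.14, adjusted p = 0.0424), the sodium channel Scn10a (0.58, SE 0.12), the granulocyte genes Mpo (0.57, SE 0.13) and Ly6g2 (0.56, SE 0.11) and the chemokine receptor Cxcr1 (0.56, SE 0.11). Apart from Lpar6, at 10.18 ± 0.2 (SD, n = 4) in KO_CD3, these were dim, at 5.70 to 7.17 in KO_CD3. Each of the 5 lost its call without 5 to 7 of the 8 arrays in turn (adjusted p up to 0.171) and under at least 1 other scaling.

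Under anti-CD3 plus anti-CD28, Bhlhe40 was the 1 gene that differed between genotypes in limma, with 0 higher and 1 lower. An unadjusted p under 0.05 was found for 545 genes, below the share of 0.05 of 16427 genes that chance would give. The block also gave 1, with 1016 at an unadjusted p under 0.05, above that share. Of genes at the centre of the CD28 response none was called: Il2 differed by -0.49 (95% interval -1.26 to 0.29), Il2ra by 0.01 (-0.40 to 0.41), Myc by -0.11 (-0.39 to 0.16), Mki67 by -0.18 (-0.76 to 0.40), Bcl2l1 by -0.21 (-0.88 to 0.46), Ctla4 by 0.02 (-0.45 to 0.48), Ifng by -0.27 (-0.71 to 0.18) and Tnfrsf4 by -0.04 (-0.59 to 0.52). The widest intervals were those of Il3 (-1.28, -3.02 to 0.46) and Csf2 (-0.42, -1.46 to 0.61). All 10 had an adjusted p of 0.999 in the fit without the block. Within each replicate number Il2 and Il3 were lower in knockout than in wild type, but with the block neither was called. Il2ra, Myc, Mki67, Ctla4, Ifng, Tnfrsf4 and Csf2 differed in sign between the numbers. Il3 passed with replicates 1 and 2 alone (-1.37, adjusted p = 0.0382). In simulated data limma recovered 79.1% of 1.5-fold and 98.5% of 2-fold changes in this comparison. These shares are averages over genes drawn at random, with 200 changed at once. They do not hold for genes that spread as widely as Il3 and Csf2.

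No list had a member called here over all genes, and adjusted over the list alone 1 B cell marker was higher. Camera called 8 lists at small shifts. Mitosis had a median of -0.17 (adjusted p = 1.8e-07, and adjusted p = 0.46 with an estimated correlation), with Aurka, a mitotic kinase, at -0.29 (unadjusted p = 0.00663). DNA replication had a median of -0.07 (adjusted p = 0.0023, and adjusted p = 0.68 with an estimated correlation), with a mean difference of -0.08 (95% interval -0.39 to 0.23). Cholesterol synthesis (median -0.06, 0.0072), NF-kB targets (-0.10, 0.0072), MYC and ribosome biogenesis (-0.07, 0.029), interferon response (-0.05, 0.0072) and activation receptors (-0.04, 0.047) were lower and B cell markers (0.12, 0.029) higher. With an estimated correlation they had adjusted p = 0.63, 0.63, 0.68, 0.46, 0.46 and 0.46. With the replicate block cytokines (0.05), glycolysis (0.033) and helper lineage factors (0.035) were called as well, and with an estimated correlation these had adjusted p = 0.48, 0.55 and 0.48. The calls of mitosis and DNA replication held whichever array was left out and after quantile normalization, where with the interferon list 3 lists were called in all.

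Arrays that ended the other list calls were WT_CD3CD28 replicate 1 for cholesterol synthesis (0.39), KO_CD3CD28 replicates 1 and 2 and WT_CD3CD28 replicate 3 for interferon response (up to 0.28) and KO_CD3CD28 replicates 1, 3 and 4 and WT_CD3CD28 replicates 1 and 3 for activation receptors (up to 0.4). MYC and NF-kB lists were lost without WT_CD3CD28 replicates 1 or 2 or KO_CD3CD28 replicates 3 or 4 (up to 0.81 and 0.51), and B cell markers without WT_CD3CD28 replicates 1 or 4 or KO_CD3CD28 replicates 2 or 3 (up to 0.099). The 15 lists without a call had adjusted p from 0.063 to 0.91. Of these, amino acid and ATF4 genes (0.0067 at the lowest), glycolysis (0.0025) and helper lineage factors (0.015) passed without KO_CD3CD28 replicates 1 or 2 or WT_CD3CD28 replicate 4, AP-1, NFAT and immediate early genes without KO_CD3CD28 replicate 1 or WT_CD3CD28 replicate 4 (0.011) and cytokines without KO_CD3CD28 replicate 2 or WT_CD3CD28 replicate 4 (0.027).

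Of the genes that CD28 changed in wild type, 1 was called in the opposite direction in the knockout under anti-CD3 plus anti-CD28, Bhlhe40, and 0 in the same direction. It is the gene deleted in the knockout, so its direction follows from the genotype. Among the 50 tested genes on each side of Bhlhe40 on its chromosome, in the gene order of assembly GRCm38.p6, 1 of 100 was called under anti-CD3 (Suclg2, named since it was the only one) against 167 of 16326 elsewhere (two-sided Fisher's exact test, p = 1). Under anti-CD3 plus anti-CD28 none of the 100 was.

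The interaction asked whether the CD28 effect differed between genotypes. limma called 0 genes, with 867 at an unadjusted p under 0.05, and a smallest adjusted p of 0.905. The 867 are close to the share of 0.05 of 16427 genes that chance would give. With the replicate block limma called 0, with 1642 at an unadjusted p under 0.05, above that share. The lowest adjusted p of the genes given here was then 0.0942 for Spry1 and Bhlhe40 and 0.164 for Orc1 and Rrs1. Without the block Bhlhe40, near background in knockout, had a difference of -1.59 (95% interval -2.41 to -0.78, adjusted p = 0.905). Orc1 had a difference of 0.78 (95% interval 0.46 to 1.11), Spry1 of 0.70 (0.38 to 1.03), the ribosome assembly factor Rrs1 of 0.75 (0.40 to 1.10), Mcm3 of 1.02 (0.46 to 1.58), Mcm5 of 0.92 (0.41 to 1.42), Myc of 0.48 (0.10 to 0.87) and Ctla4 of 0.85 (0.20 to 1.5), all with an adjusted p of 0.905. Il2 had -0.09 (-1.19 to 1.01), Il3 -1.16 (-3.62 to 1.30) and Il2ra 0.57 (0.00 to 1.14). With replicates 1 and 2 alone 80 genes were called, and with replicates 3 and 4 alone 0. With the block, leaving out KO_CD3CD28 replicate 3 gave 34 and leaving out replicate 4 of either group with CD28 gave 1.

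Camera called 9 lists with a higher CD28 effect in knockout than in wild type. DNA replication and G1/S had a median of 0.65 (adjusted p = 4.8e-24, and adjusted p = 0.2 with an estimated correlation), with 0 members called and 24 adjusted over the list alone. Its mean level had an interaction of 0.59 (95% interval 0.15 to 1.03), which was 0.69 within replicates 1 and 2 and 0.48 (-0.30 to 1.26) within replicates 3 and 4. An interaction equals the genotype effect under anti-CD3 plus anti-CD28 minus that under anti-CD3. For this list these were -0.08 and -0.67, so it mostly restates the lower knockout level under anti-CD3. The other lists were MYC and ribosome biogenesis (median 0.32, 1.7e-08, 1 member adjusted over the list alone), mitosis (0.43, 7.9e-06, 0 members), activation receptors (0.22, 0.001, 0), amino acid and ATF4 genes (0.23, 0.0015, 0), glycolysis (0.28, 0.0026, 0), cholesterol synthesis (0.14, 0.011, 0), AP-1, NFAT and immediate early genes (0.21, 0.035, 1) and regulatory T cell markers (0.16, 0.043, 0). With an estimated correlation these 8 had adjusted p = 0.42, 0.46, 0.15, 0.46, 0.42, 0.52, 0.42 and 0.42.

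Leaving out WT_CD3CD28 replicate 4 or KO_CD3 replicate 4 ended the calls of the amino acid and glycolysis lists (up to 0.079 and 0.069) and, with KO_CD3 replicate 2, of cholesterol synthesis (up to 0.19), which also missed the threshold after quantile normalization (0.074). The regulatory T cell list was lost without WT_CD3 replicates 1 or 2, KO_CD3 replicates 2, 3 or 4, WT_CD3CD28 replicates 2 or 4 or KO_CD3CD28 replicates 2 or 4 (up to 0.16). The AP-1, NFAT and immediate early list was lost without WT_CD3 replicates 1 or 3, KO_CD3 replicates 2, 3 or 4, WT_CD3CD28 replicates 2 or 4 or KO_CD3CD28 replicate 1 (up to 0.29). With the block the erythroid and platelet list was also called (median -0.14, 0.044), with an adjusted p = 0.38 at an estimated correlation. It was also called, unblocked, without WT_CD3 replicates 1 or 2, KO_CD3 replicate 3 or KO_CD3CD28 replicates 2 or 3 (0.025 at the lowest). Naive and quiescence genes passed after quantile normalization (0.021). The 14 lists without a call had adjusted p from 0.053 to 1.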

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

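All patterns weighed here were chosen after the results were seen. The tests of replicate sets and of the CD28 axis and that of T cell identity were written before their own values were known. The Xist, scaling and whole-cause tests of the first pattern and the array splits were written after.

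Some values stood apart from the other 3 of their group. Of 219 groups of 4 values examined, 18 met the Dixon criterion, where 10.9 would at 1 in 20. Sex-linked genes account for 8: in WT_CD3 replicate 1 Xist was 10.95, Kdm5d 6.01, Eif2s3y 4.38 and Uty 4.36, and in WT_CD3CD28 replicate 1 they were 11.23, 6.11, 4.52 and 4.46. KO replicates 2 and 4 had the same pattern, which the criterion cannot single out since there are 2 of them. In both genotypes the Xist level follows the replicate number across the 2 stimuli.

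The others were smaller, and about as many as 1 in 20 would give by chance. WT_CD3 replicate 3 was high in Dtl (9.06, others at most 8.42) and Lig1 (9.65, others at most 9.11), and WT_CD3 replicate 4 low in Mthfd2 (9.68, others at least 10.05) and Nop58 (11.10, others at least 11.27). KO_CD3 replicate 2 was high in Il7r (12.45, others at most 12.21), KO_CD3 replicate 3 low in Nop58 (10.59, others at least 10.85) and KO_CD3 replicate 4 low in Txnip (11.91, others at least 12.18). With CD28, Bub1 was at 11.19 in WT replicate 4 (others at most 10.85), Klf3 at 9.11 in WT replicate 3 (at most 8.92) and Spry1 at 7.87 in KO replicate 1 (at most 7.68).

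Camera called 9 lists in the interaction although limma called 0 genes: DNA replication (adjusted p = 4.8e-24), MYC and ribosome biogenesis (1.7e-08), mitosis (7.9e-06), activation receptors (0.001), amino acid and ATF4 genes (0.0015), glycolysis (0.0026), cholesterol synthesis (0.011), AP-1, NFAT and immediate early genes (0.035) and regulatory T cell markers (0.043). With an estimated correlation none was called.

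Probes outside the tested genes, 9807 in number, were also fitted with limma: 1999 (20.4%) were called for the CD28 effect in wild type, 3254 (33.2%) in knockout and 5 between genotypes under anti-CD3. They lack a single gene symbol and are not interpreted.

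The first pattern is the lower DNA replication list in knockout under anti-CD3, by -0.67. With the Xist level as a covariate the difference was -0.65, but 1 slope served both stimuli, so a sex effect under anti-CD3 alone was not removed. Among WT_CD3 arrays with low Xist the list was at 8.81, 9.38 and 8.87, against 8.19 and 8.61 in KO_CD3. With high Xist it was at 8.85 against 7.99 and 8.46. These values argue against an uneven sex of the donors as the whole source. Uneven distributions of the deposited values are excluded, at -0.65 after quantile normalization. RMA had already normalized quantiles, so a second round cannot test a shift that the first brought in. Cells other than T cells among the knockout cells cannot be told. The T cell identity list differed by -0.21, and its interval reaches from 0.01 to -0.44. As the whole cause, such cells would lower this list about as far as the DNA replication list. Its interval stops short of -0.67, which argues against them as the whole cause. The list also fell with CD28 in wild type and does not track cell content alone. Such cells are therefore not excluded as a part of the cause. A delayed or smaller entry into the cell cycle remains possible.

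The second is the CD28 response that differs between replicates 1 and 2 and replicates 3 and 4. These sets came from the first component of the same arrays, so their test is not independent, and with only 3 ways to part 4 numbers no share can fall under 0.05. Of 635 genes, 444 were still called after quantile normalization, which excludes uneven distributions of the deposited values as the source of those 444. A shift brought in by RMA itself is not tested by this. Myeloid cells cannot be told: their list's CD28 effect differed by -0.08 (95% interval -0.33 to 0.18). Separate days of culture or lots of beads are possible, and the labels give neither.

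In the last pattern, on the CD28 axis, genes that CD28 raises in wild type lie lower in knockout under anti-CD3. The genotype effect on the CD28 effect had a covariance of -0.0365 and a slope of -0.166 over all genes. It was -0.0636 with a slope of -0.225 for replicates 1 and 2 alone, and 0.0014 with a slope of 0.00667 for replicates 3 and 4 alone. Both effects use the same WT_CD3 arrays within each set, which pushes the covariance up. The value of replicates 3 and 4 thus shows neither the pattern nor its absence. Shared WT_CD3 arrays are excluded, since they push the covariance up (0.00887 to 0.0128 in simulated data) and separate arrays gave -0.0231 to -0.0615. Uneven distributions of the deposited values are excluded at a slope of -0.165 after quantile normalization, but not a shift brought in by RMA itself.

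Array splits tested whether the groups' arrays part by genotype or stimulus more than by chance. Of 35 splits of 8 arrays, 1 called as many genes as the CD28 effect in wild type and 1 as many as in knockout, in each case the real one, with at most 0 in any other. For the genotype under anti-CD3 2 of 35 did, the other being that of replicates 1 and 2 against 3 and 4, with 490 genes. Under anti-CD3 plus anti-CD28 3 of 35 did, and the same parting called 2049. By these shares, chance is not excluded as a source of the gene counts in either genotype comparison. Among the 8 splits that part every pair, no other called a gene in either comparison. The real split alone is already 1 of these 8, so they are too few to exclude chance. For the interaction the draws can tell nothing, since any of the 100 calls at least the real count of 0 (2129 at the highest).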

How the results depend on the processing

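The alternatives on replicate sets and on the Xist level, and the leave-outs with the replicate block, were chosen after the results were seen.

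The count of 169 genes between genotypes under anti-CD3 depends on the model. Median centring gave 261, array weights 597, every probe on its own 30, and a fit of only the 2 groups compared 5. The replicate block gave 1954, the replicate set as a term 1254, the set with its interaction 2150, the Xist level 49 and the block with the Xist level 1247. Replicates 1 and 2 alone gave 1388 and replicates 3 and 4 alone 0. At least 1.5-fold were 77, and 6 passed an adjusted p of 0.01. Leaving out 1 array gave 7 to 452, and 262 to 1918 with the block. Bhlhe40 differed by -1.99 with replicates 3 and 4 alone (limma adjusted p = 0.0969).

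Counts of the CD28 effect moved by smaller factors. In wild type replicates 3 and 4 alone gave 2650 genes and at least 1.5-fold 2205, with leave-outs at 3947 to 4983. In knockout these were 2896, 2907 and 5171 to 6242, and every probe on its own gave 9853. Between genotypes under anti-CD3 plus anti-CD28, the replicate set with its interaction gave 2 and replicates 1 and 2 alone 2, with leave-outs at 1. The interaction had 16 genes with the set and its interaction, 80 with replicates 1 and 2 alone, 1 with the block and the Xist level, and 0 to 34 in leave-outs with the block.

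Lists called with an estimated correlation were 3 and 0 for the CD28 effect in wild type and knockout, 1 and 0 for the genotype under anti-CD3 and with CD28, and 0 for the interaction, against 9, 13, 11, 8 and 9. Fry called 14 in wild type, 0 for the genotype with CD28 and 0 for the interaction. For the genotype with CD28 quantile normalization gave 3 lists, replicates 3 and 4 alone 13, and leave-outs 3 to 12. Leave-outs of the interaction gave 4 to 10. For genes and lists whose values are given in the results, the replicate block changed no call in that comparison beyond those stated there.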

Other observations

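Genes and tests in this part were chosen after the results were seen.

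CD28 also changed single genes that the results leave out. In wild type the clock repressor Per1 fell by 0.7 on the log2 scale (SE 0.13, limma adjusted p = 0.000519) and the clock output Dbp by 0.37 (adjusted p = 0.0128). The transcription factor Irf8 rose by 1.86 (SE 0.28), the hexokinase Hk2 by 1.83 (SE 0.31) and the asparagine synthetase Asns by 1.88 (SE 0.37). The anergy-associated factor Egr2 fell by 1.1 (SE 0.18) and the B cell coactivator Pou2af1 by 1.31 (SE 0.14), while chemokine receptors parted, with Ccr4 higher by 1.12 (SE 0.21) and Cxcr4 lower by -1.34 (SE 0.26).

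Over all genes, the genotype effect under anti-CD3 ran against the CD28 effect in wild type, with a slope of -0.166, and of -0.165 after quantile normalization. It was -0.225 with replicates 1 and 2 alone and 0.00667 with replicates 3 and 4 alone. With separate WT_CD3 arrays for the 2 effects the covariance stayed below 0 (-0.0231 to -0.0615). A pooled slope below 0 could arise if knockout cells had gone less far in the response to anti-CD3. That was not tested, since no unstimulated or earlier sample was measured. The genotype effects of replicates 1, 2 and 3 had covariances of -0.0495, -0.0636 and -0.0438 with the CD28 effect averaged over all 4 numbers. That of replicate 4 had 0.0108, a value that simulated unchanged groups with shared arrays also gave (0.00887 to 0.0128).

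Fewer differences were called with CD28. Under anti-CD3 plus anti-CD28 the DNA replication list differed by -0.08 (95% interval -0.39 to 0.23) and Il2 by -0.49, and Bhlhe40, the gene that CD28 raised 3.86-fold in wild type, was alone in the comparison. Cytokines reported to depend on Dec1 in later T helper cells, such as Csf2, spread too widely here for a difference to be excluded (-0.42, 95% interval -1.46 to 0.61). The spread of Csf2 followed the replicate sets. With CD28, replicates 1 and 2 held it at 7.57 and 7.82 in wild type and at 6.96 and 6.89 in knockout. In replicates 3 and 4 it was at 5.39 and 5.5 against 5.21 and 5.52, near background, where a difference could not show. Cultures at later times, with donors of known sex, would tell a delay from a lasting difference.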
